A study of Mus musculus with 4 samples.

How the data were processed

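RNA from chemically transformed C3H10T1/2 mouse fibroblasts was labelled with Cy3 (500 ng of RNA per sample, per the labels) and hybridised to a custom Agilent mouse array, 1 sample per array. Groups were taken from the treatment label: 2 untreated and 2 DEM-exposed samples, numbered as in the labels. The duration of DEM exposure is not given in the sources used here. Spot intensity values were read per the file headers from Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), which had subtracted background with a spatial detrend, applied a multiplicative detrend and replaced low signals by surrogate values on all 4 arrays. The mark for a spot well above background was the one set by that software, with a multiplier of 13 per the file headers. The deposited series table holds log2 values by the authors; its column medians were -4.39 and -4.35 (untreated) and -4.30 and -4.36 (DEM), and at least 99.98% of probes in each column lay within 0.01 of log2 processed signal minus a constant, the 75th percentile of the array. Scale and centring of that table were therefore settled from the values, and it was used as an alternative.

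Each array had 62976 spots, of which 1319 were controls and were left out, as were spots carrying an outlier mark (13 to 68 per array; 130 probes left out). No spot was saturated. Processed signal was transformed to log2, and the 75th percentile over non-control probes was subtracted per array. Replicate spots of a probe were averaged, giving 61307 probes, of which 40628 were gene probes and 20679 NONCODE transcript probes. Of the gene probes, 34524 were matched to a current symbol in the RefSeq gene table of GRCm38.p6 (28136 by accession, 4982 by symbol and 1406 by synonym) and 6104 kept the name in the files. That table served for names only; the array design names no build, so no coordinates are given. Probes well above background on at least 2 of 4 arrays were kept (31845), and the brightest probe stood for each gene, which left 24658 genes and transcripts. Of 5551 with several kept probes, 4206 had all probes in the same direction; among the 1758 of these that passed, 158 had a probe in the other direction.

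Groups were compared with limma 3.58.1 in R 4.3.3 (data.table package, version 1.17.8; figures with matplotlib 3.10.9) by lmFit and eBayes with an intensity trend, with no covariate, 2 residual degrees of freedom and 4.04 prior degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. A gene not well above background on both arrays of one group has only a lower bound on its fold, the mean of the bright group over the mean of the higher of the dim probe's own level and the lowest level among probes well above background on each array (log2 -4.81 to -4.15). Such folds are written as at least N-fold, and 247 higher and 606 lower genes have them.

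Gene lists (20 pathway lists and 9 lists of cell type markers), the tests and most alternative settings were fixed before the data were examined. Lists with at least 5 measured members were tested with camera (preset correlation 0.01, trended variance), adjusted over the pathway lists and separately over the marker lists, with camera using an estimated correlation and with fry beside it. fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. With an estimated correlation, camera takes its p from a t distribution on the 2 residual degrees of freedom, so few lists can pass after adjustment. Named genes followed a rule fixed in advance. It took the 10 highest and 10 lowest log2 fold changes among genes of plain symbol that passed, changed at least 2-fold, were well above background on all 4 arrays and had both DEM arrays beyond both untreated arrays. It added the 3 largest lower bounds per direction, 22 genes named whatever their result, and up to 4 members with the smallest p in each list. A few genes under this rule are not reported here one by one; they stay in the counts and list tests. Names outside this rule, and the gene families defined by symbol stem (at least 10 measured members), were chosen after their values were seen. Symbols of opposite-strand transcripts were taken out of the families after the family results had been seen, because such a transcript is not a member of the family its name carries. This lowered the families tested from 142 to 141 and those with an adjusted p under 0.05 from 21 to 20, and it dropped the Fzd family (6 of 10 members lower, adjusted p = 0.00118), which then had under 10 members.

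Settings fixed in advance as alternatives were normexp background correction (offset 50), quantile and median normalization, the authors' processed values, no filter on dim probes, a filter for all 4 arrays, the mean of all kept probes of a gene, eBayes without a trend, the replicate number as a block, and each array left out in turn. With 1 array left in a group, that array is assumed to vary like those of the other group. Added after seeing the data were the 75th percentile over probes well above background on all 4 arrays and scaling to 7 detected spike-in probes. Cyclic loess normalization and list tests against genes with a plain symbol were also added then. Slide and scan time did not vary (1 slide, 1 scan time), so a block for them was not run.

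The procedure was tested on simulated data of this comparison with 24658 genes. With 50 genes changed per size, 0% were recovered at a log2 change of 0.5, 0% at 1, 40% at 2 and 74% at 3, with 3 false calls and 0 of the wrong sign. With 5000 genes changed by between 1 and 3 on the log2 scale, 89.3% were recovered and 4.2% of 4663 calls were false. Smaller changes were not part of that run, and genes were simulated independently of each other.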

Results

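RNA levels were measured on 4 one-colour microarrays in C3H10T1/2 cells, a mouse embryo fibroblast line used to score chemical transformation. The cells had been transformed in culture with the polycyclic hydrocarbon carcinogen MCA (2.5 µg/ml for 2 days) followed by the phorbol ester TPA (100 ng/ml for 2 weeks). Untreated transformed cells (2 arrays) were compared with transformed cells exposed to 0.25 mM diethyl maleate (DEM, 2 arrays), an electrophile that binds and depletes glutathione. Each array carried 61657 probe spots. Between 47.8% and 52.7% of all spots were well above background on an array, and the 75th percentile of signal was 701 and 747 on the untreated arrays and 449.9 and 412 on the DEM arrays. Levels are log2 signal minus the 75th percentile of the array. The correlation across probes was 0.987 between the untreated arrays and 0.982 between the DEM arrays, against 0.935 to 0.946 between an untreated and a DEM array. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

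The comparison asked what DEM did to gene expression in transformed cells, with glutathione, MAPK and cancer pathways named in the title of the series. DEM-exposed cells had more RNA of the glutathione synthesis genes Gclc, Gclm and Gss. They also had more RNA of most measured genes controlled by NRF2, the transcription factor that responds to electrophiles. The list of glutathione metabolism genes as a whole was not shifted relative to other genes. Of 37 measured NRF2 target genes, 31 rose and 0 fell. Interferon response genes moved the other way, with 28 of 30 lower, and 23 of 34 extracellular matrix genes were lower. Most measured genes of the heat shock response rose (17 of 23), while cytokine and cholesterol synthesis genes mostly fell. MAPK cascade members showed no common shift.

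Of 24658 genes and transcripts tested, 3825 were higher and 2893 lower with DEM at an adjusted p under 0.05 (limma, n = 2 arrays per group), and 2143 and 2395 of these changed by at least 2-fold. Among the 12686 genes with a plain symbol (no clone, predicted, NONCODE or accession-like name), 2145 rose and 2086 fell. Both DEM arrays lay beyond both untreated arrays for 16877 genes (68.4%), where chance alone gives 33.3%. Far fewer genes passed without either untreated array, and more passed without either DEM array. A fit that leaves 1 array in a group takes its variance from the other pair alone. The DEM pair differed more (SD of the difference 0.635) than the untreated pair (0.521). Calls lost or gained in such fits, here and below, therefore do not by themselves show that a result rests on the array left out. The division between higher and lower depended on scaling. Higher genes made up 56.9% of those changed, against 46.9% after quantile normalization and 40.8% after cyclic loess, so small shifts are relative to the scaling used. With normexp background correction 6531 genes were higher and 1470 at least 2-fold lower, and with cyclic loess 2529 were higher. With no filter on dim probes 17309 were higher, and the median over all genes was 0.47, against 0.16 with the filter. Camera compares a list with other genes. List calls gained or lost with no filter, here and below, may therefore come from the other genes. With scaling to spike-in RNA 358 were higher and 863 lower. Under the spike-in scaling, 16 NRF2 targets, 3 heat shock genes and 4 ATF4 targets were higher, and 14 matrix and 2 cholesterol synthesis genes were lower. That scaling moves the arrays of each group apart as a whole. The 75th percentile minus the spike-in level was -2.77 and -3.42 (untreated) and -2.79 and -3.71 (DEM). Calls of single genes lost under it, here and below, may therefore come from that wider spread alone.

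The genes named here for glutathione synthesis rose. Slc7a11, the cystine transporter subunit that supplies its cysteine, rose by 7.12 ± 0.27 on the log2 scale (SE, n = 2 per group), or 139-fold (adjusted p = 0.000647). Gclc and Gclm, the catalytic and modifier subunits of glutamate cysteine ligase, rose 12.2-fold (log2 3.61 ± 0.19) and 11.8-fold (3.56 ± 0.24). Glutathione synthetase, Gss, rose 6.30-fold and glutathione reductase, Gsr, which regenerates the reduced form, 5.27-fold. Among glutathione S-transferases, which join glutathione to electrophiles, Gsta1 rose from a mean level of -4.18 ± 0.37 to 5.01 ± 0.02 (SD, n = 2), a 585-fold change (adjusted p = 0.000425). Gsta3 rose 135-fold, and Gsta2, not well above background in untreated cells, was at least 390.2-fold higher. Gsta1 and Gsta2 are near-identical in sequence and Gsta3 is a close relative, so their probes may share signal. The whole list of glutathione metabolism genes was not shifted relative to other genes (camera adjusted p = 0.559), with a median log2 change of 0.34. Of 43 measured, 17 rose, 11 fell and 15 did not pass (18 and 14 when adjusted over the list alone). fry, which does not compare the list with other genes, gave an adjusted p of 0.0348. Without untreated 1 the list had 10 higher and 6 lower members, and without untreated 2 it had 12 and 5. Scaling to spike-in RNA gave the list an upward shift (adjusted p = 0.00266) with 9 higher and 7 lower members, and 7 were lower among probes well above background on 4 arrays.

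**Figure D1:**
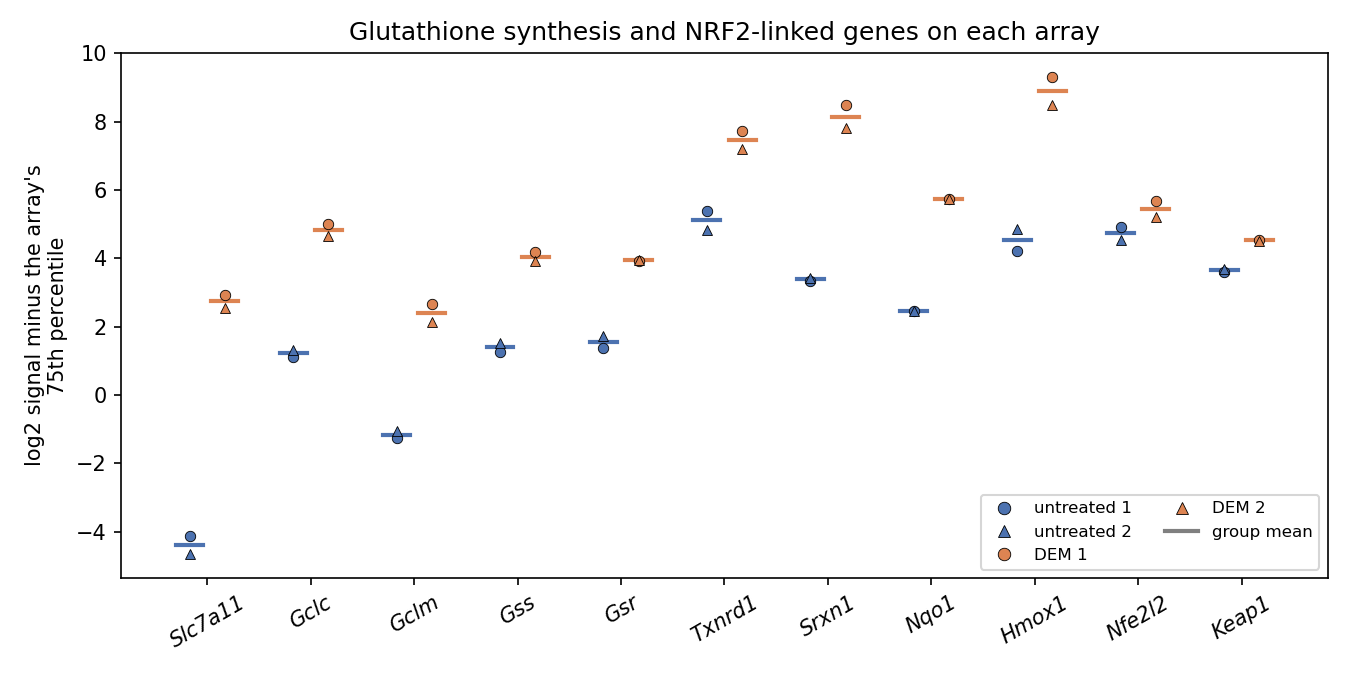
Level of 11 named glutathione synthesis and NRF2-linked genes on each array, as log2 signal minus the 75th percentile of the array; points are arrays (circles replicate 1, triangles replicate 2) and bars are group means. Among the 11 genes plotted, Slc7a11 moved furthest, by 7.12 log2 units, while Nfe2l2 differed by 0.71 and did not pass the test.

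NRF2 target genes rose as a group. Of 37 measured, 31 rose, 0 fell and 6 did not pass, and 32 rose when adjusted over the list alone; the median change was 1.92 on the log2 scale (camera adjusted p = 1.34e-16, and adjusted p = 0.235 with an estimated correlation). The list shares 8 measured genes with glutathione metabolism. Hmox1, which degrades heme, rose 20.5-fold (log2 4.36 ± 0.33, adjusted p = 0.00121). Srxn1, which repairs oxidized peroxiredoxins, rose 26.9-fold, Blvrb, a biliverdin reductase, 13.4-fold, Nqo1, a quinone reductase, 9.65-fold and Txnrd1, thioredoxin reductase, 5.12-fold. Keap1, the protein that holds NRF2 in check, rose 1.84-fold (adjusted p = 0.0114), but did not pass without untreated 1 (adjusted p = 0.0953), without untreated 2 (adjusted p = 0.0848) or with scaling to spike-in RNA. Nfe2l2, which encodes NRF2, differed by 0.71 ± 0.22 and did not pass (adjusted p = 0.0631), though it did without DEM 2 (adjusted p = 0.0168) and among probes well above background on 4 arrays (adjusted p = 0.0494).

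Stress response lists rose alongside. Of 23 measured heat shock genes, 17 rose, 0 fell and 6 did not pass, and 19 rose when adjusted over the list alone (camera adjusted p = 1.05e-07, and adjusted p = 0.341 with an estimated correlation). The chaperones Hsph1 and Hspb1 rose 7.15-fold and 4.72-fold, and the mitochondrial chaperonin Hspd1 2.65-fold. Of 34 measured targets of ATF4, the transcription factor of the integrated stress response, 20 rose, 1 fell and 13 did not pass (22 and 1 when adjusted over the list alone; camera adjusted p = 2.11e-06, and adjusted p = 0.332 with an estimated correlation). Asns, asparagine synthetase, rose 2.69-fold, and the glycine transporter Slc6a9 3.92-fold. Of 13 metallothionein and metal handling genes, 8 rose, 1 fell and 4 did not pass (9 and 2 when adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.332 with an estimated correlation). Metallothionein Mt2 rose 5.95-fold, the ferritin light chain Ftl1 3.41-fold and the transferrin receptor Tfrc 4.18-fold. Without untreated 1, 11 heat shock, 7 ATF4 and 5 metal handling genes were higher, and without untreated 2, 10, 12 and 6 were. With scaling to spike-in RNA 3 metal handling genes were higher, and Hspd1, Asns, Slc6a9, Ftl1 and Tfrc did not pass (adjusted p between 0.126 and 0.461). The metal handling call was lost with normexp (adjusted p = 0.0562) and with no filter on dim probes (adjusted p = 0.293).

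Targets of p53 and of the aryl hydrocarbon receptor (AHR) were shifted upward less firmly. Of 28 measured p53 targets, 11 rose, 4 fell and 13 did not pass (15 and 4 when adjusted over the list alone; camera adjusted p = 0.0268, and adjusted p = 0.332 with an estimated correlation). Plk2 rose 3.61-fold and Mdm2, the ubiquitin ligase that limits p53, 2.25-fold, while Sesn1 fell by 1.76 on the log2 scale. Cdkn1a, the cell cycle inhibitor p21, rose 1.92-fold (adjusted p = 0.0269), and Trp53 itself differed by 0.26 ± 0.28 and did not pass. Without untreated 1, 2 p53 targets were higher and 1 lower, without untreated 2, 2 and 2, and the Cdkn1a call was lost in both (adjusted p = 0.154 and 0.0582). Cdkn1a also did not pass after quantile normalization (adjusted p = 0.0592), after cyclic loess (adjusted p = 0.0625), with scaling to spike-in RNA (adjusted p = 0.974) or without the variance trend (adjusted p = 0.0561). The Mdm2 call was also lost in both (adjusted p = 0.0599 and 0.0512). With scaling to spike-in RNA 0 p53 targets were higher and 0 lower, with adjusted p of 0.191 for Plk2, 0.782 for Mdm2 and 0.122 for Sesn1. Of 9 measured AHR genes, 4 rose, 0 fell and 5 did not pass (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0275, and adjusted p = 0.332 with an estimated correlation). Cyp1a1, a hydrocarbon-metabolizing enzyme, was not well above background in untreated cells and was at least 8.38-fold higher. Of the other higher AHR genes, Gsta1, Nqo1 and Aldh3a1 are also in the NRF2 list, and Aldh3a1 did not pass without untreated 1 (adjusted p = 0.144) or untreated 2 (adjusted p = 0.0701), or with scaling to spike-in RNA (adjusted p = 0.822). Both lists lost the call with normexp (adjusted p = 0.16 and 0.0664) and with no filter on dim probes (adjusted p = 0.409 and 0.21). The p53 call was also lost with scaling to spike-in RNA (adjusted p = 0.162), and the AHR call with only probes well above background on 4 arrays (adjusted p = 0.139).

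Interferon response genes, which encode antiviral proteins, had the largest fall among the pathway lists. Of 30 measured, 28 fell, 0 rose and 2 did not pass, and 29 fell when adjusted over the list alone; the median change was -2.95 on the log2 scale, or -2.80 with 3 members at their lower bound (camera adjusted p = 1.43e-20, and adjusted p = 0.126 with an estimated correlation). Ifit3 fell by 3.79 ± 0.19 on the log2 scale, the RNA helicase gene Dhx58 fell by 3.69 ± 0.20 and Ifit1 fell by 3.64 ± 0.21. The oligoadenylate synthetase genes Oasl2 (-5.33) and Oas2 (-5.17) fell further. Without untreated 1 the list had 19 lower members and without untreated 2 it had 18, with medians of -3.10 and -2.78; with normexp the median was -2.25.

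Inflammatory cytokine and NF-kB target genes fell as well. Of 27 measured, 16 fell, 1 rose and 10 did not pass, with the same counts when adjusted over the list alone; the median change was -1.63, or -1.31 with 5 members at their lower bound (camera adjusted p = 1.67e-07, and adjusted p = 0.169 with an estimated correlation). The chemokine genes Cxcl1 (log2 change -2.73) and Ccl7 (-2.33) fell. Il33 was not well above background with DEM and was at least 6.20-fold lower. Ptgs2, the inducible cyclooxygenase, was the member that rose, by 6.50-fold (adjusted p = 0.000994). Without untreated 1 or untreated 2, 10 or 11 members were lower. The median was -0.77, with 11 of 22 lower, among probes well above background on 4 arrays, and -0.68, with 7 of 36 higher and 16 lower, with no filter on dim probes; the list stayed shifted downward in both (adjusted p = 7.18e-06 and 7.1e-08).

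**Figure D2:**
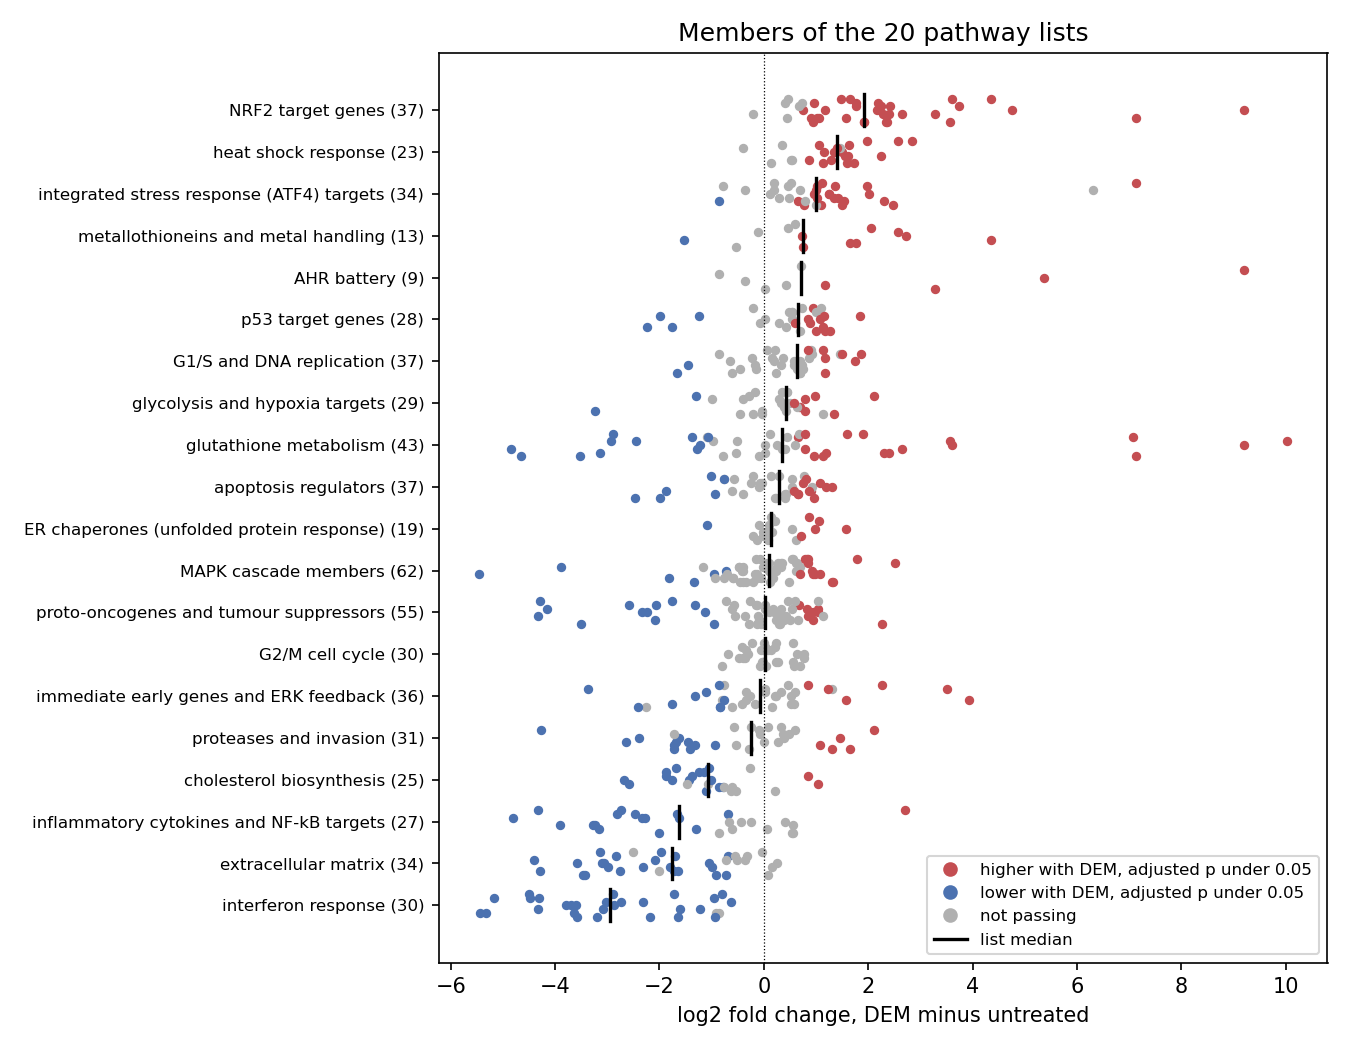
Log2 fold change (DEM minus untreated) of each measured member of the 20 pathway lists, with the number measured in parentheses; red points rose, blue points fell, grey points did not pass, and black bars are list medians. Interferon response genes have the lowest median (-2.95) and NRF2 target genes the highest (1.92).

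Extracellular matrix genes were lower in DEM-exposed cells. Of 34 measured, 23 fell, 0 rose and 11 did not pass, and 26 fell when adjusted over the list alone; the median change was -1.76, or -1.72 with 1 member at its lower bound (camera adjusted p = 1.32e-13, and adjusted p = 0.126 with an estimated correlation). The collagen genes Col11a1 (log2 change -4.41 ± 0.21) and Col3a1 (-2.76 ± 0.20) fell, the matricellular gene Thbs2 fell by 3.58 ± 0.18, and smooth muscle actin, Acta2, fell by 3.47 ± 0.15. Without untreated 1 the list had 12 lower members, and without untreated 2 it had 15. Of 31 measured protease and invasion genes, 5 rose, 11 fell and 15 did not pass (5 and 12 when adjusted over the list alone), with a median of -0.24, or -0.10 with 1 member at its lower bound (camera adjusted p = 0.0358, and adjusted p = 0.332 with an estimated correlation). The protease inhibitor Timp3 fell by 4.28 and the aggrecanase Adamts5 fell by 2.40, whereas the urokinase receptor gene Plaur rose 4.30-fold. That list's call was lost without untreated 1, against genes with a plain symbol alone (adjusted p = 0.117) and with the percentile taken over detected probes (adjusted p = 0.0522). With no filter on dim probes its median turned to 0.05 and 8 members were higher, while the test stayed downward (adjusted p = 0.00115). It had 5 lower members without untreated 1 and 6 without untreated 2, and with scaling to spike-in RNA 0 higher and 3 lower, where Plaur did not pass (adjusted p = 0.0832).

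Several measured markers of fibroblasts and of muscle fell with the matrix genes. The matrix list also holds 5 of the fibroblast and 2 of the smooth muscle markers. Of 10 measured fibroblast markers, 5 fell, 0 rose and 5 did not pass, with 5 lower when adjusted over the list alone (camera adjusted p = 0.00144, and adjusted p = 0.157 with an estimated correlation). The platelet-derived growth factor receptor genes Pdgfrb (log2 change -1.81) and Pdgfra (-1.33) fell, and the proteoglycan gene Dcn fell by 3.11. The calls of Pdgfra and Dcn were lost without untreated 1 (adjusted p = 0.0616 and 0.0645) and without untreated 2 (adjusted p = 0.0528 and 0.0705). Lower fibroblast markers numbered 1 without untreated 1, 2 without untreated 2 and 2 with scaling to spike-in RNA, where Pdgfrb and Pdgfra did not pass (adjusted p = 0.0879 and 0.378). All 4 measured skeletal muscle markers fell, with the same number when adjusted over the list alone. Actc1 fell by 3.75 and Acta1 fell by 3.61, and Tnnt1 was at least 12.04-fold lower. The list had 9 markers, and Myod1, Myog, Myf5, Ckm and Myh3 were not well above background on at least 2 arrays. Of 4 smooth muscle markers 2 fell, or 3 when adjusted over the list alone, and of 3 chondrocyte markers 2 fell, or 3 when adjusted over the list alone, among them Col2a1, which fell by 2.85. Of 6 osteoblast markers 1 rose and 3 fell, or 2 and 3 when adjusted over the list alone (camera adjusted p = 0.133, and adjusted p = 0.264 with an estimated correlation). Of 4 macrophage markers 1 fell (Lyz2, by 1.85), as did 1 of 4 adipocyte markers (Lpl, by 1.13) and the 1 endothelial marker measured (Tek, at least 1.22-fold lower), with the same numbers when adjusted over each list alone. The calls of those 3 genes were lost without untreated 1 (adjusted p = 0.103, 0.0709 and 0.0884) and without untreated 2 (adjusted p = 0.0925, 0.0713 and 0.0963), and with scaling to spike-in RNA; the Tek call was also lost with normexp (adjusted p = 0.182). None of 3 epithelial markers passed the limma test, adjusted over all genes or over the list alone, and Krt8, Krt14 and Krt5 had unadjusted p of 0.187, 0.193 and 0.851; with normexp, Krt14 and Krt5 passed (adjusted p = 0.029 and 0.0334), as did Krt14 without DEM 2 (adjusted p = 0.0449). Lists with under 5 measured markers had no list test.

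Cholesterol synthesis genes were lower with DEM. Of 25 measured, 15 fell, 2 rose and 8 did not pass (20 and 2 when adjusted over the list alone), with a median of -1.06 (camera adjusted p = 2.64e-07, and adjusted p = 0.378 with an estimated correlation; fry adjusted p = 0.058). The sterol reductase gene Dhcr7 fell by 2.69 on the log2 scale, and Fdps, which makes farnesyl diphosphate, fell by 1.68. Fewer members passed without either untreated array, where the DEM pair alone sets the variance. Dhcr7 had a log2 change of -2.58 without untreated 2 and did not pass there. Fdps did not pass with scaling to spike-in RNA (adjusted p = 0.159).

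MAPK cascade genes had no common direction. Of 62 measured, 13 rose, 6 fell and 43 did not pass (15 and 6 when adjusted over the list alone); the median was 0.09, the mean -0.03 and the test direction down (camera adjusted p = 0.816), and the median turned to -0.12 with the mean of all probes of a gene. The kinase ERK1 (Mapk3, -0.71 ± 0.23) did not pass (adjusted p = 0.0652). Mapk3 passed with normexp, quantile, loess and detected-probe scaling (adjusted p between 0.0272 and 0.0358) and without DEM 2 (adjusted p = 0.0353). Map2k6, a kinase upstream of p38, was at least 15.6-fold lower, the receptor gene Fgfr2 was at least 3.33-fold lower, and the stress-induced gene Gadd45g rose 2.46-fold. Without either untreated array, 3 members were higher and 3 lower. Of 36 immediate early and ERK feedback genes, 6 rose, 9 fell and 21 did not pass (6 and 11 when adjusted over the list alone; camera adjusted p = 0.33). The AP-1 gene Fosl1 rose 15.2-fold and the MAPK phosphatase gene Dusp4 rose 11.4-fold, whereas the feedback inhibitor Spry1 fell by 3.37 and the nuclear receptor Nr4a1 fell by 2.40. Egr1 fell by 0.76 (adjusted p = 0.0163), but did not pass without untreated 1 (adjusted p = 0.107), without untreated 2 (adjusted p = 0.129) or with scaling to spike-in RNA. Fos (-2.26 ± 0.66), Dusp1 (-0.60 ± 0.34) and Dusp6 (0.15 ± 0.17) did not pass, Fos with an adjusted p of 0.0519. The DEM arrays disagreed on Fos (SD 1.47), which changed by -1.22 without DEM 1 and by -3.30 without DEM 2. Leaving out a DEM array removes that disagreement from the variance, so passing there was no support. With both DEM arrays kept, Fos passed with normexp, with probes well above background on 4 arrays and with detected-probe, spike-in and loess scaling (adjusted p between 0.0242 and 0.0491). Lower members numbered 3 without untreated 1 and 2 without untreated 2. With scaling to spike-in RNA 1 MAPK gene was higher and 2 lower, 2 immediate early genes were higher and 3 lower, and Gadd45g did not pass (adjusted p = 0.531). With normexp 10 immediate early genes were higher. With no filter on dim probes, the MAPK and immediate early lists were shifted downward relative to other genes (camera adjusted p = 0.0194 and 0.00223). The medians of these lists were then 0.10 and -0.07, against 0.47 over all genes.

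Proto-oncogenes and tumour suppressors were mixed. Of 55 measured, 8 rose, 13 fell and 34 did not pass (8 and 14 when adjusted over the list alone). The median was 0.02, the mean -0.36 and the test direction down (camera adjusted p = 0.241, fry adjusted p = 0.0208). Myc, a driver of cell growth, rose 4.82-fold (log2 2.27 ± 0.30, adjusted p = 0.00529). The growth factor genes Tgfb2 (log2 change -2.58) and Vegfc (-2.24) fell, and Hgf was at least 4.27-fold lower. Without untreated 1 the list had 1 higher and 7 lower members, and without untreated 2 it had 1 and 8. With scaling to spike-in RNA it had 0 and 6, and Myc did not pass (adjusted p = 0.0608). Higher members numbered 4 after cyclic loess, and 8 were lower among probes well above background on 4 arrays. The list's downward shift passed with normexp (adjusted p = 0.0222) and with scaling to spike-in RNA (adjusted p = 0.0406). It also passed with no filter on dim probes (adjusted p = 0.00486), where the list's own median was 0.18, against 0.47 over all genes.

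G2/M genes of the cell cycle differed between the DEM arrays more than between the groups. None of 30 measured G2/M genes passed the limma test, adjusted over all genes or over the list alone, and the smallest unadjusted p in the list was 0.0903 (Cdca8); the median was 0.02, the mean 0.05 and the test direction down (camera adjusted p = 0.684). The median level of these genes relative to their mean over the arrays was -0.79 on DEM 1 and 0.74 on DEM 2, against -0.03 and 0.02 on the untreated arrays. Leaving out a DEM array removes the disagreement between the DEM arrays from the variance. Calls made without DEM 1 or DEM 2, also for the G1/S genes below, are therefore no support for a shift of a list. With no filter on dim probes the G2/M list was shifted downward relative to other genes (camera adjusted p = 0.0248). The list's own median stayed at 0.02 with 0 calls, while the median over all genes went from 0.16 to 0.47. The proliferation marker Mki67 differed by 0.01 ± 0.62 over the 4 arrays, by 1.05 without DEM 1 and by -1.02 without DEM 2. Of 37 measured G1/S and replication genes, 7 rose, 2 fell and 28 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.147), and without DEM 1 the numbers were 23 and 2 (adjusted p = 1.63e-05). Without DEM 2 they were 7 and 6, and the test direction was down (adjusted p = 0.809). Pcna, the replication clamp, rose 2.20-fold, and Ccnd1, the G1 cyclin D1, fell by 1.66 (adjusted p = 0.0103). Without untreated 1, 1 G1/S member was higher and 0 lower, and Ccnd1 did not pass (adjusted p = 0.0531). Without untreated 2, 0 passed in either direction, with adjusted p of 0.0784 for Ccnd1 and 0.0622 for Pcna. With scaling to spike-in RNA 0 passed either, with adjusted p of 0.157 for Ccnd1 and 0.77 for Pcna, and after cyclic loess 4 were higher.

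**Figure D3:**
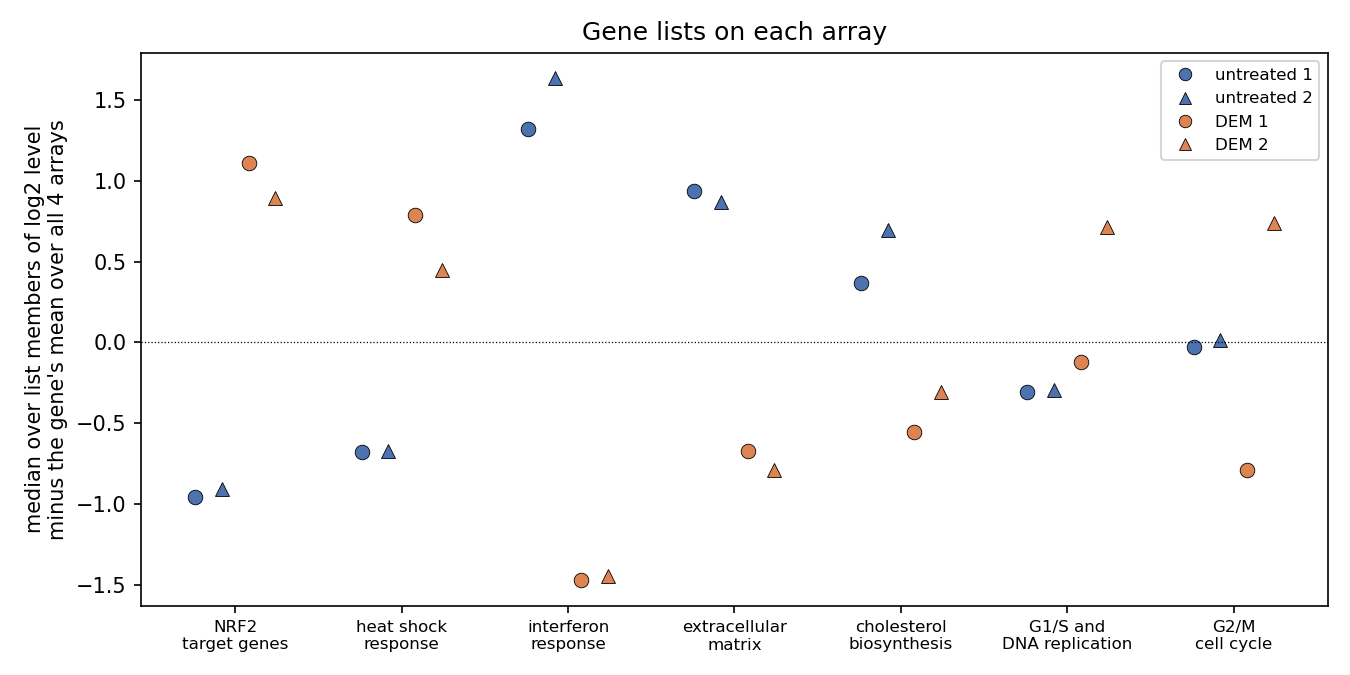
Median over the members of each list of the log2 level minus the gene's own mean over the 4 arrays, per array (circles replicate 1, triangles replicate 2). The DEM arrays lie together for NRF2 targets (1.11 and 0.89) and interferon response genes (-1.47 and -1.44) but apart for G2/M genes (-0.79 and 0.74).

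The remaining lists were not shifted relative to other genes by camera. fry, which makes no such comparison, gave adjusted p of 0.00782 for chaperones of the endoplasmic reticulum, 0.058 for apoptosis and 0.416 for glycolysis. Of 37 measured apoptosis regulators, 11 rose, 6 fell and 20 did not pass (13 and 7 when adjusted over the list alone; camera adjusted p = 0.684). Cytochrome c, Cycs, rose 2.29-fold, while the death receptor gene Fas (log2 change -1.99) and the BH3-only gene Bmf (-2.47) fell. Higher apoptosis regulators numbered 4 after quantile normalization and 5 after cyclic loess, and higher glycolysis genes 3 and 2. Of 29 glycolysis and hypoxia genes, 7 rose, 2 fell and 20 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.197); 13 were higher without DEM 2 (adjusted p = 0.0123). The glucose transporter Slc2a1 rose 4.31-fold, and Epas1, a hypoxia-inducible transcription factor, fell by 3.23. Of 19 endoplasmic reticulum chaperone genes, 5 rose, 1 fell and 13 did not pass (7 and 1 when adjusted over the list alone; camera adjusted p = 0.249), among them Dnajb9, which rose 3.00-fold. Without untreated 1, the numbers higher and lower were 1 and 2 for apoptosis, 2 and 1 for glycolysis and 2 and 0 for chaperones, and Fas did not pass (adjusted p = 0.0505). Without untreated 2 they were 1 and 3, 1 and 2, and 1 and 0, and Cycs did not pass (adjusted p = 0.0617). With scaling to spike-in RNA they were 0 and 1, 0 and 1, and 0 and 0, with adjusted p of 0.712 for Cycs, 0.0606 for Fas, 0.0777 for Slc2a1 and 0.435 for Dnajb9.

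Beyond these lists, the genes with the largest rises among those well above background on 4 arrays included Dnmt3l, a cofactor of DNA methylation in germ cells (36.8-fold, log2 5.20 ± 0.29), the cell adhesion gene Nrcam (23.9-fold), Nyx (22.97-fold), the pluripotent cell gene Dppa5a (19.97-fold) and Afp, alpha-fetoprotein (18.5-fold). Glyat was at least 39.8-fold and Akr1c18 at least 33.5-fold higher, both not well above background in untreated cells. The largest falls were of Prelp, a matrix proteoglycan gene (-5.42 ± 0.32), Serpina3g (-5.29), the nucleic acid sensor gene Zbp1 (-5.22), Fgf18 (-5.08), Olfml3 (-5.06), Phactr1 (-5.00), Tmem119 (-5.00) and the interferon-inducible GTPase gene Iigp1 (-4.99). Islr, Lrrc17 and Selenbp1 were at least 95.5-fold, 87.3-fold and 80.5-fold lower, and Selenbp1 has a near-identical paralog whose signal its probe may share. The 20 genes with the largest rises and falls had adjusted p between 0.000425 and 0.00157.

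With 2 arrays per group, the number of arrays limits the precision of each value. All arrays came from 1 slide, with untreated arrays in one row and DEM arrays in the other, so position on the slide and treatment cannot be told apart. In the set tests, 11 of 20 pathway lists were shifted by camera with a preset correlation and 13 by fry. With an estimated correlation 0 were, and the smallest unadjusted p was 0.011. That test rests on the 2 residual degrees of freedom, so almost no list can pass it after adjustment. The matrix list had an estimated correlation of -0.0201, below the preset 0.01, yet its camera adjusted p went from 1.32e-13 to 0.126. Calls lost under that test therefore do not by themselves show that gene correlation made the shifts. The estimated correlation was above the preset for cholesterol (0.401), heat shock (0.349), ATF4 (0.159) and NRF2 (0.112) genes. For these lists correlation may make the p with the preset value too small. The estimate was near the preset for interferon (0.0114) and AHR (0.0237) genes. It was below the preset for the NF-kB, metal handling, p53 and protease lists.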

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

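The spike-in, cyclic loess and detected-probe scalings and the list test against plain symbols were chosen after the data were seen. The other alternatives were planned. The directions of the NRF2, interferon, matrix, heat shock, ATF4, cholesterol and NF-kB lists held under every scaling, filter and left-out array. Genes higher with DEM numbered 3825, against 6531 with normexp (1470 at least 2-fold lower, from 2395), 17309 with no filter on dim probes, which tests more genes, and 2529 with cyclic loess. With spike-in scaling 358 were higher and 863 lower, all of them at least 2-fold. Only 7 probes set that scale, and 17.2% of the calls were kept. The 75th percentile minus the spike-in level was -2.77 and -3.42 on the untreated arrays and -2.79 and -3.71 on the DEM arrays. Relative to percentile scaling, this adds an array-wide difference within each group to every gene. It widens the spread and so lowers the number of calls. Leaving out 1 array gave 648 to 4474 higher and 801 to 3791 lower, and 648 to 2618 and 801 to 2953 at least 2-fold; the low ends come without an untreated array, and without a DEM array 4464 and 4474 were higher. Higher genes made up 56.9% of the changed genes, 46.9% after quantile normalization, 42.0% with the percentile over detected probes, 40.8% after cyclic loess, 29.3% with spike-ins, 70.2% with normexp and 84.7% with no filter. The median over all genes, 0.16, moved by -0.16, -0.15 and -0.156 with the detected-probe, loess and spike-in scalings. It moved by 0.309 with no filter on dim probes. Of the 20 lists, 11 were shifted, 0 with an estimated correlation and 9 to 13 under all other settings. A fit without an untreated array takes its variance from the DEM pair alone, and spike-in scaling widens the spread within each group. Except where a construction is named, the cause was not tested.

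Some named genes changed sign. Mki67 (0.01) was -0.038 with normexp, -0.19 with quantile, -0.030 with median scaling, -0.096 with the mean of probes, -0.15 with detected probes, -0.14 with spike-ins and -0.20 with loess, and ran from -1.02 to 1.05 over left-out arrays. Dusp6 (0.15) was -0.032 with quantile, -0.0085 with detected probes, -0.0051 with spike-ins and -0.065 with loess. Krt5 (0.06) was -0.052 with the mean of probes, -0.096 with detected probes and -0.092 with spike-ins. Krt8 was 0.062 and Myh11 0.36 with normexp. Over left-out arrays Krt5 ran from -0.11 to 0.24, Trp53 from -0.10 to 0.63, Aurka from -0.083 to 1.46, Aif1 from -0.89 to 0.20 and Myh11 from -2.26 to 1.05. None of these genes passed the limma test over the 4 arrays. Of 138 named genes, 43 lost their call with spike-in scaling, 21 without untreated 1, 25 without untreated 2 and at most 4 under any other setting; the filter for 4 arrays measured 118 of them.

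The labels do not pair arrays by replicate number. Over genes, deviations of arrays numbered 1 correlated at 0.0844 after percentile scaling, which removes array-wide differences. The mean log2 spike-in level was higher on the arrays numbered 2 (untreated 12.95, DEM 12.39) than on those numbered 1 (12.21 and 11.59). The correlation therefore cannot rule out a link by number. With a replicate block 4515 genes were higher and 3389 lower, and 11 lists were shifted; no named gene lost its call, and 5 gained one, namely Nfe2l2 (adjusted p = 0.0119), Fos (0.00215), Mapk3 (0.0188), Sox9 (0.0205) and Smtn (0.0386). Fewer spots were well above background on the DEM arrays (49.2% and 47.8%) than on the untreated ones (52.3% and 52.7%), so folds of dim genes are bounds.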

Other observations

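Gene families defined by symbol stem were chosen after the data were seen, and so were the named members below. Of 141 families tested with camera, 20 had an adjusted p under 0.05 with the preset correlation and 0 with an estimated one (adjusted p = 0.859 at the lowest). With 2 residual degrees of freedom, almost no family can pass that second test after adjustment. The guanylate-binding protein genes, GTPases induced by interferon, were lower: 10 of 11 fell, with a median of -3.42, or -2.38 with members at their lower bound (adjusted p = 4.91e-08). Of 13 protocadherin beta genes, which encode cell adhesion proteins of a clustered locus, 12 fell and 0 rose (median -1.34, adjusted p = 2.81e-07); members of both families are close in sequence and may share signal, and their medians over 6 scalings ran from -3.58 to -1.73 and from -1.50 to -0.99. Of 11 Adamts protease genes 8 fell (adjusted p = 8.72e-06), led by Adamts9, which fell by 4.42 on the log2 scale. fry gave adjusted p of 0.0118 for the guanylate-binding protein, 0.052 for the protocadherin beta and 0.0114 for the Adamts genes. The estimated correlation of the protocadherin beta genes was 0.299, above the preset 0.01.

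Genes of the 19S proteasome cap moved upward. Of 14 Psmd genes 10 rose and 0 fell (median 1.09; adjusted p = 0.000856, and adjusted p = 0.859 with an estimated correlation), among them Psmd11, by 3.03-fold, and Psmd7, by 2.59-fold; the median stayed between 0.85 and 1.04 over the scalings. Camera also gave an upward shift for the Exosc genes of the RNA exosome, of which 5 of 10 rose and 0 fell (adjusted p = 0.0152). Of 19 nucleoporin genes 9 rose and 0 fell (camera adjusted p = 0.0194). Of 11 Utp genes of ribosome assembly 6 rose and 1, Utp14b, was lower (camera adjusted p = 0.0458). fry gave adjusted p of 0.0365 for the Psmd, 0.0438 for the Exosc, 0.062 for the nucleoporin and 0.0611 for the Utp genes. One feature stood apart: Slc3a2, the partner subunit of Slc7a11, was 4.83 on untreated 1 and -3.76 on untreated 2, against 7.06 and 6.62 with DEM, and did not pass (adjusted p = 0.111).

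The tests of macrophage markers, of another cell type, of spike-in brightness and of the size of the interferon shift were chosen after the results were seen; the other tests were set beforehand. With percentile scaling, bright genes were mostly higher with DEM: above a mean level of 4, 897 rose and 137 fell, so 86.75% of changed bright genes were higher against 51.5% of the others, a gap of 35.2 percentage points. This depended on the scaling, as 50.7% of changed bright genes were higher after quantile normalization and 49.3% after cyclic loess, against 46.2% and 39.2% of the others (gaps of 4.55 and 10.05 points). Quantile normalization makes brightness distributions equal by construction, so the test settles nothing about the source. A hybridization or scan response that depends on brightness is argued against by 7 spike-in probes, where the 3 bright ones changed by -0.0382 relative to the others, between -0.0457 and -0.0308 over pairs of arrays, against 0.152 for genes. A difference in labelling or RNA composition between samples stays open and may matter for small changes.

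For the interferon response genes, by the rule set beforehand, at least 20 lower members without any array, the count depended on single arrays: 18 were lower without untreated 2 and 19 without untreated 1, while the list median nearest to 0 was -2.78. That rule counts calls, and without an untreated array the DEM pair alone sets the variance, so a lower count may come from that. Lower expression of the interferon receptor and its kinases is argued against, as Ifnar1, Ifnar2, Jak1 and Tyk2 had a median of 0.12, with Ifnar1 at 0.63 and Ifnar2 at -0.10. Macrophages in the untreated cultures are argued against as the source of the whole shift: of 12 markers, 1 was well above background on both untreated arrays and at least 2-fold lower (Lyz2, by 1.85). Cd14 (0.32 ± 0.23), Cd68 (0.28 ± 0.25) and Aif1 (-0.34 ± 0.39) lay far from the median of the interferon list, and the other 8, among them Ptprc, Tyrobp and Csf1r, were not well above background on both untreated arrays. A share too small to raise those markers was not tested, and an effect of DEM itself may be the source.

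A replacement of the fibroblasts by 1 of the 8 other listed cell types is argued against as the whole source of the fall in matrix genes. Cell types without a marker list were not tested. Of 8 other marker lists, with 1 to 6 measured markers each, 0 had most of them higher, and 0 had more markers well above background on both DEM arrays than on both untreated arrays. With normexp 2 of 3 epithelial markers were higher (Krt14 by 0.58 and Krt5 by 0.38), but of 11 listed, 2 were well above background on both DEM arrays and 3 on both untreated arrays. Lower TGF-beta signalling may contribute, and the test was undecided: of 12 early target genes 3 fell and 0 rose, with Ltbp2 at a log2 change of -3.60, Ccn2 at -3.05 and Tgfb1i1 at -1.39, while Smad7 (0.17) did not pass; Ccn2 is also in the matrix list, so it is not independent. Slide position, shared with treatment, stays open for each pattern.

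Dnmt3l and Dppa5a, genes of germ and pluripotent cells, were among the largest rises. As a hypothesis, release of genes silenced by promoter methylation might raise germline genes as a class. Of 24 listed germline genes 5 were measured, and 1 was higher (Tex19.2, by 1.18) and 0 lower, too few to decide.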
